A study of Mus musculus with 10 samples.

How the data were processed

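The 10 samples were dura cells of 3 groups: 3 control, 4 LM day 7 and 3 LM day 12 libraries. Per the labels, the dura was dissected and digested with a collagenase and a DNase, the cells were strained, and libraries were made with the BD Rhapsody system and sequenced on a NovaSeq instrument. The values are raw counts of molecules (UMI) per gene and cell, as deposited by the authors, with no scaling or log applied; they were whole numbers whose sums differed between cells and libraries. The submitters' processing notes name Seurat 4.3.0 and the genome build mm10, and the aligner, the counting tool and the rule for calling cells are not given in the sources used here. Each library held 31253 gene rows and between 5169 and 14675 barcodes, and the least UMI count of a barcode was 449 to 501. Counting intervals and floors (3 counts) cover counting error only.

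Barcodes with under 200 detected genes or over 25% mitochondrial counts were removed, from 59 to 779 per library. Cells with a scrublet doublet score over 0.2 (scanpy 1.11.5), 0.780% to 2.99% of a library, were also removed. Counts were scaled per cell and log transformed, and 2000 variable genes were chosen by mean rank over libraries, without mitochondrial, ribosomal protein, haemoglobin, sex-linked and immune receptor segment genes. From 30 principal components a shared neighbour graph with 20 neighbours was clustered with the Leiden method (leidenalg 0.10.2, resolution 1.0, seed 1), with no correction between libraries. Clusters were named from marker sets for 24 cell classes when at least 3 markers were detected in 10% of the cells and higher than in all other cells, and no other class had more markers among the 10 leading genes. Clusters in conflict were split at resolution 2.0.

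The groups, comparisons, tests, marker sets, gene lists and alternative settings were fixed before the data were examined. The doublet score, the bounds for the Y-negative class (10% of the control level of Y-linked transcripts) and the Tph1-high class (1000 counts per 1000000), the rule for mixed clusters (over 5% doublets and at least 5 markers of another class) and the splitting of clusters in conflict were set after the data were seen.

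Cells per class and library were compared with edgeR 4.0.16 (quasi-likelihood test, total cells as library size) for 16 classes, with Benjamini-Hochberg adjustment over classes and a threshold of 0.05. An exact permutation test of the between-group F statistic on arcsine square root shares used all 4200 assignments of 10 libraries to the 3 groups, and two-sided exact permutation tests, with p as double the smaller tail, compared pairs of groups. Counts were summed per class and library for 7 classes, leaving out libraries with under 20 cells of the class, which removed LM day 12 library 3 (12 cells) for fibroblasts. Sums were filtered with filterByExpr, scaled with TMM factors and compared in edgeR with a robust quasi-likelihood fit of all 3 groups; p-values were adjusted over the genes tested. CPM are counts per 1000000 with TMM factors, and errors of log2 fold changes were computed from the fold change and the F statistic. The ratio for a gene with 1 to 3 counts in a group is given with its exact conditional interval. Genes were located in the GRCm38 annotation.

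There were 28 gene lists, fixed by name and class. Each was tested in its classes with camera (limma 3.58.1) at a preset correlation of 0.01 on log CPM with a prior count of 2, with camera at an estimated correlation and with fry, adjusted over the lists and 3 comparisons of a class. Of 318 list tests, 148 passed with the preset correlation, 2 with the estimated correlation and 33 by fry; where a list passed, its median and its test had the same sign. The genes named in the text come from a fixed rule: per class and comparison, among genes past the threshold with a mean of at least 20 CPM and no overlap between the groups, the 8 largest rises and the 8 largest falls without predicted, ribosomal, mitochondrial and receptor segment genes, and from each list the 4 members with the smallest p. The text names 78 of the combinations of gene, class and comparison that this rule gives, from the top of a ranking in each case; which rankings were used was decided after the values were seen. Of the combinations given by the rule, 1 that would have been named is not reported here.

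Alternatives fixed beforehand were DESeq2 1.42.0, size factors in place of TMM, TMM factors over the classes, no filter on low counts, a stricter cell filter (400 genes, 15% mitochondrial counts), resolutions 0.5 and 2.0, doublets kept, leukocytes only, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were Y-negative cells, and also Tph1-high and choroid plexus cells or macrophages, left out of the total; a permutation test of the absolute difference; the cells of 1 cluster of a class only; and free RNA subtracted. For the last, the share of a library's pooled counts within a class was taken as the median, over markers of other classes with at least 50 CPM in the pool, of their level in the class over that in the pool, and this share of the pool was taken off the sums. The share was 13.9% to 20.1% in LM day 12 library 1, 0% (B lineage cells) to 13.0% in library 2, and 6.76% to 15.1% in library 3. It was 19.2% to 24.2% in LM day 7 library 1. In LM day 12 library 2 Xist, the X-linked transcript of female cells, stood at 99.3 CPM in neutrophils and 205 CPM in Y-negative cells. The neutrophil share there was 13.0%, so the estimate was too low for Xist in that class. The subtraction may thus take off too little RNA of Y-negative cells. As the pool was that of all cells, the estimate holds for RNA set free in proportion to it.

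The fits were tested on simulated data. With counts drawn from the real class means and library sizes and changes set at LM day 12, edgeR recovered 33.3% of 2-fold and 96.0% of 4-fold changes in macrophages against control, with 6 of 134 calls false, and 24.0% and 76.0% in fibroblasts, with 1 of 101 calls false. Against LM day 7 it recovered 45.8% and 97.0% in macrophages and 25.0% and 72.0% in fibroblasts, with 7 of 148 and 4 of 101 calls false, and it made 0 calls between LM day 7 and control, where nothing was changed. For shares, simulated at a dispersion of 0.1, 96.3% of 4-fold changes were recovered, with 0.220 false calls per run. This recovery holds for that spread, and changes in shares that spread more between libraries would be recovered less often. In the self-test of the list test, 2 of 20 unchanged lists in macrophages and 0 of 20 in fibroblasts had a p under 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.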

Results

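The series measured gene expression in single cells of the mouse dura, the outer membrane around the brain. Cells came from control mice and from mice of the LM group, which the series title equates with leptomeningeal metastasis, the spread of tumour cells to the inner membranes and the fluid around the brain. There were 3 control libraries, 4 LM libraries of day 7 and 3 LM libraries of day 12. Libraries were made with the BD Rhapsody system, which traps cells in microwells and tags each captured transcript with a unique molecular identifier (UMI), so that every count is 1 molecule. Total UMI counts were 31733910, 27362242 and 61546609 in the control libraries. They were 26922540, 27407380, 15483486 and 23736876 at LM day 7, and 68391920, 102473551 and 82831362 at LM day 12. After filtering, 73334 cells were kept, from 4901 to 13916 per library. The median was 1715 to 5168 UMIs per cell. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

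Cells were grouped into 47 clusters and named from marker genes, so that a name such as neutrophil stands for neutrophil-like cells. A pair of further classes had no marker set and were set apart by a measured property. The Tph1-high class held clusters with Tph1, an enzyme of serotonin synthesis, above 1000 counts per 1000000 (CPM). Its clusters were led by genes such as Crx, Sag and Rbp3, which are known from photoreceptors and the pineal gland. The Y-negative class held clusters 1, 4, 13 and 18, whose transcripts of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) came to at most 5.20% of the control level. The next lowest cluster was at 43.0%. Cluster 4 was led by Osr2, Dpt and Col3a1. Its cells carried fibroblast markers, 6 of them higher than in all other cells, and were not counted as fibroblasts. Cluster 13 was led by the cell division genes Ccnb1 and Cenpf and cluster 18 by Nptx1 and Hmga1. Cluster 1, led by Kcnq1ot1, Xist and Hmga2, had a median UMI count at 0.220 of that of its libraries. Unnamed cells made up 5.30% ± 1.81 (SD, n = 3) of control, 5.20% ± 3.62 (n = 4) of LM day 7 and 5.20% ± 2.70 (n = 3) of LM day 12 cells. At LM day 12, 96.9% of the unnamed cells lay in cluster 11, a low-UMI cluster with H2-Ab1 and Cd74 among its 10 leading genes.

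The comparison of LM day 12 with control asked which cells of the dura change in number in the diseased animals. Macrophages, the phagocytes resident in or recruited to tissue, rose from 3.70% ± 3.26 (SD, n = 3) of the cells kept in control to 18.7% ± 0.377 (n = 3) at LM day 12. Neutrophils, short-lived granulocytes, fell from 21.6% ± 6.87 to 5.24% ± 2.02. B lineage cells, the antibody-forming lineage with its marrow progenitors, fell from 10.6% ± 1.13 to 1.46% ± 1.38. Endothelial cells, which line vessels, fell from 14.6% ± 4.55 to 1.98% ± 1.21 and fibroblasts from 4.42% ± 0.808 to 0.367% ± 0.207. Mural cells fell from 3.26% ± 0.930 to 0.325% ± 0.300 and Schwann cells or oligodendrocytes from 3.63% ± 1.64 to 0.569% ± 0.385. Y-negative cells made up 0.0420% ± 0.0360 of control cells and 44.2% ± 11.3 of LM day 12 cells. T cells, natural killer (NK) cells and innate lymphoid cells together stood at 8.83% ± 0.939 and 10.8% ± 1.89. This difference did not pass the test (log2 fold change 0.29, SE 0.441, adjusted p = 0.517).

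**Figure D1:**
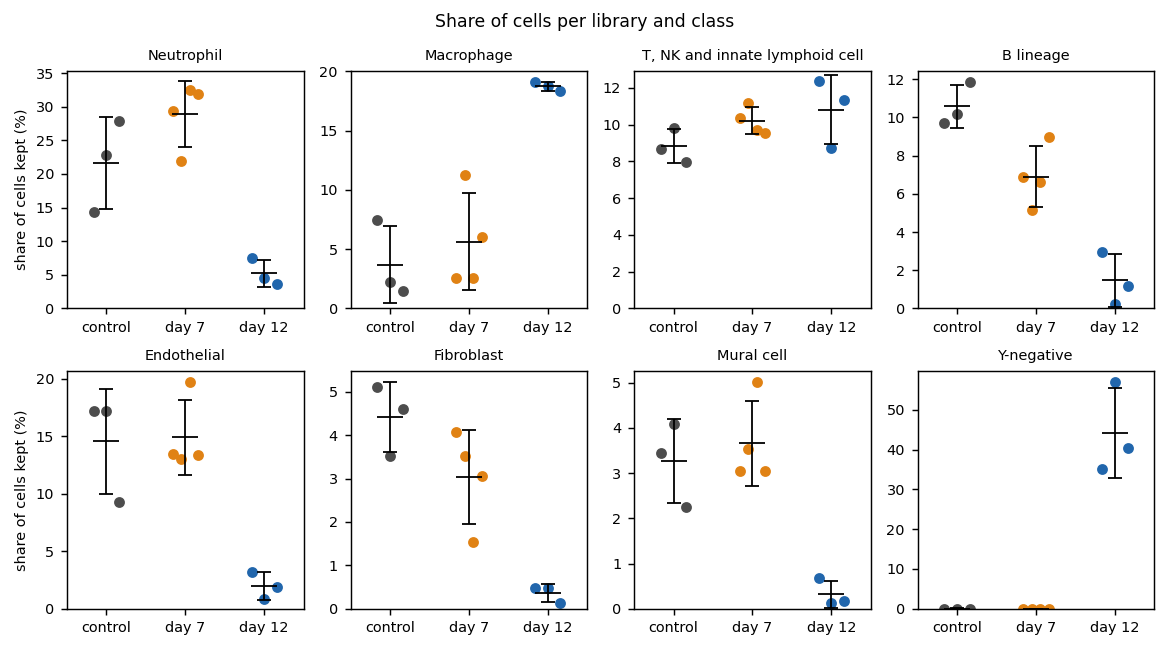
Share of the cells kept (y axis, percent) for 8 classes in control, LM day 7 and LM day 12 libraries (x axis). Each point is 1 library, with the mean as a horizontal line and the SD as the error bar; macrophages sit at 18.4% to 19.1% in the 3 LM day 12 libraries and at 1.44% to 7.43% in the control libraries.

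In edgeR's quasi-likelihood test on cells per class, 10 of 16 classes differed in share between LM day 12 and control after Benjamini-Hochberg adjustment. The log2 fold changes were 2.34 (SE 0.707, adjusted p = 0.00728) for macrophages, and -2.05 (SE 0.507, adjusted p = 0.00222) for neutrophils. They were -2.86 (SE 0.696, adjusted p = 0.00222) for B lineage cells and -2.88 (SE 0.583, adjusted p = 6.09e-04) for endothelial cells. They were -3.59 (SE 0.625) for fibroblasts, -3.35 (SE 0.653) for mural cells and -2.68 (SE 0.619) for Schwann cells or oligodendrocytes. Monocytes stood at -1.90 (SE 0.566), erythroid cells at -3.75 (SE 1.09) and Y-negative cells at 9.84 (SE 0.929, adjusted p = 2.33e-07). Over all 3 groups, an exact permutation test on arcsine square root shares with 4200 assignments gave adjusted p-values of 0.0152 for neutrophils, B lineage cells and fibroblasts. They were 0.0286 for macrophages, endothelial, mural, erythroid and Y-negative cells, 0.0312 for monocytes and Schwann cells or oligodendrocytes, and 0.0499 for the Tph1-high class (0.0565 on log shares). Between pairs of groups no permutation test passed. With p as double the smaller tail it is at least 0.100 for 3 against 3 libraries and 0.0571 for 3 against 4. On the absolute difference, a test added later, the smallest p was 0.0286 between LM day 12 and LM day 7 (adjusted p = 0.0508).

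Shares sum to 100, so the Y-negative cells lower all others. With these cells left out of the total, macrophages stood at 34.6% ± 7.69 (SD, n = 3) at LM day 12. The endothelial (log2 fold change -2.12), fibroblast (-2.67), mural (-2.60), Schwann or oligodendrocyte (-1.92), B lineage (-2.16) and neutrophil (-1.20) shares still passed. The monocyte fall did not pass (-1.04, adjusted p = 0.0858). Dendritic cells (1.35, adjusted p = 0.0230) and T, NK and innate lymphoid cells (1.14, adjusted p = 0.0193) then rose against control. With macrophages left out as well, the endothelial (-1.61), fibroblast (-2.05), mural (-2.07), Schwann or oligodendrocyte (-1.41) and B lineage (-1.67) shares passed, and the neutrophil fall did not (-0.61, adjusted p = 0.310). The macrophage call was lost without control 3 (1.95, adjusted p = 0.0529), and the erythroid call likewise (-2.26, adjusted p = 0.0830). With factors that centre the classes on each other (TMM), the neutrophil (-0.12), endothelial (-1.07), fibroblast (-1.49) and Schwann or oligodendrocyte (-0.89) falls no longer passed. Monocytes stood at 0.04. At clustering resolution 2.0 part of the macrophages were named monocytes, with macrophages at 13.9% ± 4.45 (8.87% to 17.3%) and monocytes at 5.19% ± 3.69 at LM day 12. The macrophage call was then lost (1.71, adjusted p = 0.0538), and the monocyte change turned to 1.36 (adjusted p = 0.0628).

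Between LM day 12 and LM day 7, which asks what changes within the course of the disease, macrophages rose from 5.62% ± 4.10 (SD, n = 4) to 18.7% ± 0.377 (n = 3; log2 fold change 1.74, SE 0.631, adjusted p = 0.0253). Neutrophils fell from 28.9% ± 4.90 to 5.24% ± 2.02 (-2.47) and endothelial cells from 14.9% ± 3.23 to 1.98% ± 1.21 (-2.92). Fibroblasts fell from 3.04% ± 1.08 to 0.367% ± 0.207 (-3.05) and mural cells from 3.66% ± 0.932 to 0.325% ± 0.300 (-3.52). In all, 11 of 16 classes passed in edgeR's test. The others were B lineage (-2.25), Schwann or oligodendrocyte (-2.70), monocyte (-1.57), mast cell or basophil (-1.68), myeloid progenitor (-1.70) and Y-negative cells (10.56). The macrophage call was lost without LM day 7 library 1 (1.5, adjusted p = 0.0612), 3 (1.5, adjusted p = 0.0723) or 4 (1.77, adjusted p = 0.0514). With the Y-negative cells left out the mast cell (-0.83), monocyte (-0.72) and myeloid progenitor (-0.96) falls did not pass. At clustering resolution 2.0 monocytes turned to a rise (1.66, adjusted p = 0.0214) and the macrophage call was lost (1.14, adjusted p = 0.157). With macrophages left out as well the neutrophil (-1.06, adjusted p = 0.0517) and B lineage (-1.08, adjusted p = 0.0901) falls did not pass. With TMM factors the neutrophil (-0.58), fibroblast (-1.04), B lineage (-0.84) and Schwann or oligodendrocyte (-1.04) falls did not pass.

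Between LM day 7 and control no class changed in share by edgeR's test (0 of 16), and DESeq2 called 0 as well. By each tool 1 class, erythroid cells, had an unadjusted p under 0.05 (log2 fold change -2.03 and SE 0.907 in edgeR's test). Neutrophils stood at 28.9% ± 4.90 (SD, n = 4) at LM day 7 and 21.6% ± 6.87 (n = 3) in control, B lineage cells at 6.91% ± 1.58 and 10.6% ± 1.13, and macrophages at 5.62% ± 4.10 and 3.70% ± 3.26. The Tph1-high class made up 14% ± 3.03 of control, 8.63% ± 2.22 of LM day 7 and 5.08% ± 4.32 of LM day 12 cells. Neither difference from control passed in edgeR's test.

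Transcripts of the Y-linked genes and of Xist, the X-linked transcript of female cells (chromosome X, 103460366 to 103483254, GRCm38), were counted as a check of sex. In the cells outside the Y-negative class, Y-linked genes came to 228 to 298 CPM in the control and LM day 7 libraries, with Xist at 0 to 0.320 CPM. They came to 241 and 252 CPM in LM day 12 libraries 1 and 2. In LM day 12 library 3 the Y-linked genes came to 0.0900 CPM in these cells, from 3 UMIs, and Xist to 512 CPM. This library thus had the pattern of a female animal and the other 9 that of male animals. In the Y-negative class of LM day 12 libraries 1 and 2, Y-linked genes came to 8.31 and 1.69 CPM and Xist to 276 and 205 CPM. Xist stood at 27.0 and 26.7 CPM in the other cells of the same libraries. As library 3 lacks Y transcripts in all its cells, its Y-negative cells were placed by their clusters alone. Any host fibroblasts among its 998 cells of cluster 4 are missing from its 12 named fibroblasts. Without this library, 11 classes differed in share from control, with fibroblasts at -3.18 (SE 0.609, adjusted p = 0.00123).

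**Figure D2:**
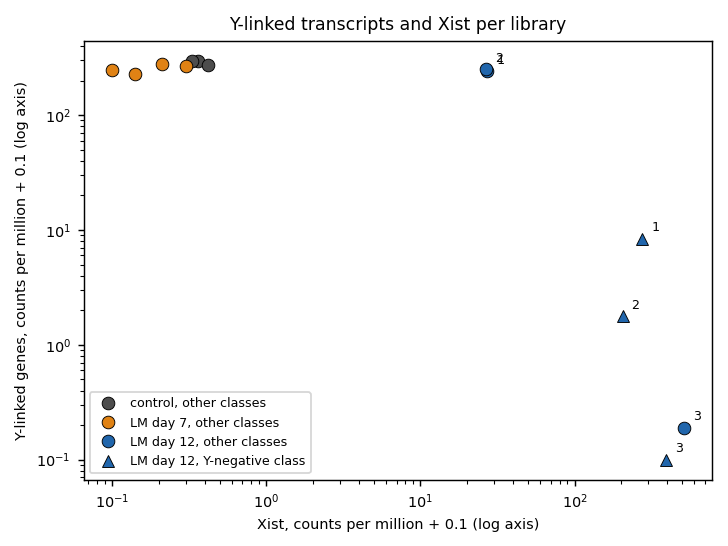
Xist (x axis) against the sum of 4 Y-linked genes (y axis), both in CPM plus 0.1 on log axes, for each library; circles are the cells outside the Y-negative class and triangles the Y-negative class of the 3 LM day 12 libraries, which are numbered. The Y-negative cells of LM day 12 libraries 1 and 2 lie at 276 and 205 CPM of Xist, and both points of library 3 lie at the lower right.

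Macrophages of LM day 12 differed from those of control in genes of sugar metabolism, of the interferon response and of tumour-associated macrophages. Arg1, arginase 1, which breaks down arginine (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, GRCm38), stood at 809 ± 247 CPM (SD, n = 3) at LM day 12 and 0.915 ± 1.59 CPM (n = 3) in control, where it rested on 1 UMI. The ratio of pooled counts was 2080, with an exact 95% interval of 374 to 82300 that covers counting error only. Lgals3, the lectin galectin-3, rose from 210 ± 60.6 to 1519 ± 61.6 CPM (log2 fold change 2.87, SE 0.252, adjusted p = 1.60e-05). Vegfa, a growth factor for vessels, rose from 3.18 ± 2.79 to 63.6 ± 27.5 CPM (3.94, SE 0.513, adjusted p = 2.41e-04). Cd163, a scavenger receptor of resident macrophages, fell from 634 ± 318 to 68.3 ± 39.5 CPM (-3.23, SE 0.614, adjusted p = 0.00684). Siglech, a receptor of microglia and plasmacytoid dendritic cells, fell as well, from 124 ± 29.7 to 1.78 ± 2.11 CPM (log2 fold change -6.11, SE 0.709; -7.70 to -5.58 over the fits without 1 library).

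Of 17 measured genes of the glycolysis and hypoxia list, 14 rose, 14 when adjusted over the list alone, among them the enzymes Tpi1 (2.01, SE 0.185, adjusted p = 1.69e-05), Gapdh (2.07, SE 0.251, adjusted p = 1.28e-04) and Ldha (1.91, SE 0.233, adjusted p = 1.32e-04). The list passed limma's camera test (adjusted p = 9.61e-11), and also passed with an estimated correlation (adjusted p = 0.0251), as it did between LM day 12 and LM day 7. No other of the 318 list tests did so. Of 12 tumour-associated macrophage genes 9 rose, 9 when adjusted over the list alone (camera adjusted p = 6.79e-06; adjusted p = 0.282 with an estimated correlation). Among them were Thbs1, thrombospondin (3.05, SE 0.465), Vegfa and Arg1. Of 14 interferon-gamma-inducible genes 7 rose, 12 when adjusted over the list alone (camera adjusted p = 6.79e-06; adjusted p = 0.436 with an estimated correlation). They included the GTPases Gbp2 (3.88, SE 0.652, adjusted p = 0.00372) and Iigp1 (1.98, SE 0.461, adjusted p = 0.0138), the latter lost without control 3 (1.33 to 2.48 over the fits without 1 library). At clustering resolution 2.0 monocytes numbered 157, 369 and 885 in LM day 12 libraries 1, 2 and 3, in place of 50, 50 and 25. Macrophages numbered 1033, 1627 and 833, in place of 1142, 1954 and 1725. A cluster then named monocyte was led by Cxcl9, Ly6i and Cxcl10. Whether the interferon genes rose in the cells still named macrophages was not tested. Of 9 resident dural macrophage genes 1 fell, Cd163, and 5 when adjusted over the list alone (camera adjusted p = 0.00818; adjusted p = 0.550 with an estimated correlation).

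In all, 817 genes rose and 1180 fell in macrophages, 1997 of 10216 tested in edgeR's test. Most macrophages of control (93.9%) and LM day 7 (94.3%) lay in cluster 12 and most of LM day 12 (88.5%) in cluster 3. Within cluster 12 alone, from only 2 of the LM day 12 libraries, 5 genes passed. In that cluster Lgals3 stood at 1.34 (adjusted p = 0.0506) and Cd163, Thbs1 and Il1rn at 0.62, -0.63 and -0.92. Tpi1, Gapdh and Ldha stood at 0.85, 0.92 and 1.25 (adjusted p = 0.189, 0.239 and 0.0876), Gbp2 at 1.25, Iigp1 at 0.35 and Siglech at -1.56. None of these passed. The median of the glycolysis and hypoxia list was 0.57 there, with 0 of 12 measured genes past the threshold, and that of the interferon-gamma-inducible list 0.35, with 0 of 11 (camera adjusted p = 0.00133 and 0.118). Of 10 measured mitochondrially encoded genes 5 fell, 6 when adjusted over the list alone (camera adjusted p = 5.73e-04; adjusted p = 0.436 with an estimated correlation). Transcripts of red cells fell too, 3 of 4 haemoglobin genes (camera adjusted p = 0.00544; adjusted p = 0.492 with an estimated correlation), among them Hbb-bt (-6.40) and Hba-a2 (-6.34). Without control 3 these stood at -3.25 and -3.0, and the calls were lost without LM day 12 library 2 or 3 for Hbb-bt and without control 1 or 3 or any 1 LM day 12 library for Hba-a2 (-7.10 to -3.25 and -7.00 to -3.0 over the fits without 1 library). With estimated free RNA taken off, 1204 genes passed, 1094 of them shared in direction with the 1997. Without control 1 there were 1017, and without the female library 1437.

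**Figure D3:**
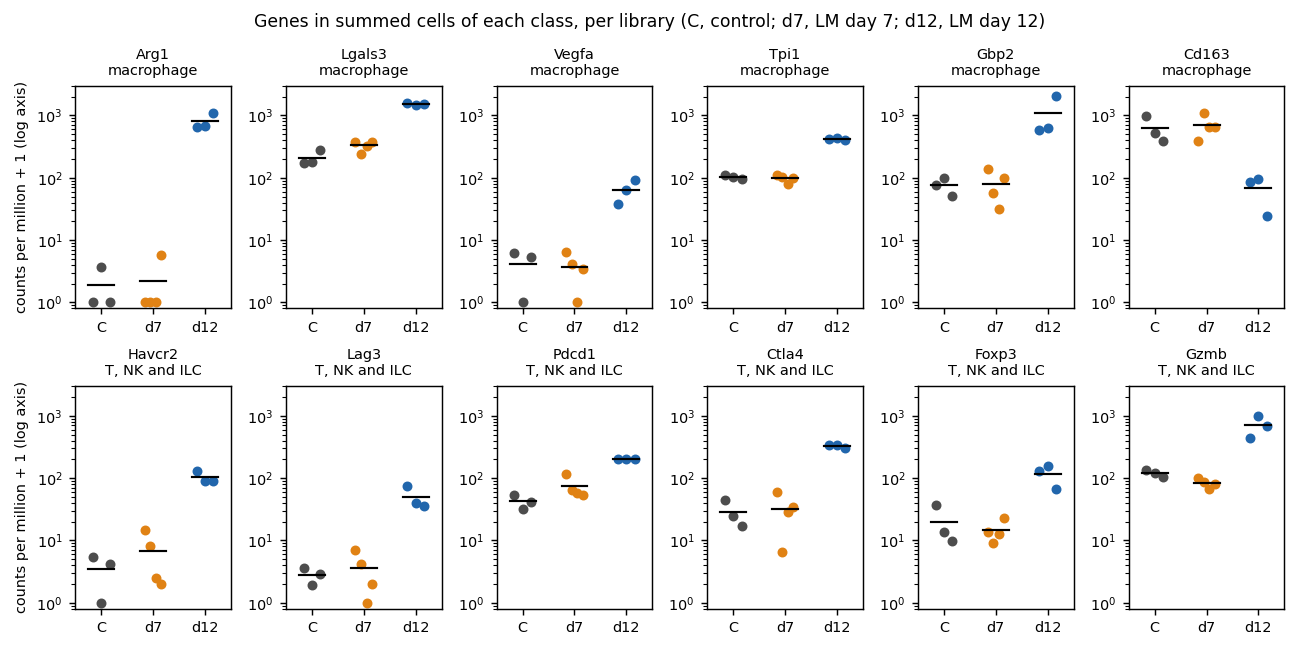
CPM plus 1 on a log axis (y axis) of 6 genes in macrophages and 6 in T, NK and innate lymphoid cells (ILC), per library, in control, LM day 7 and LM day 12 (x axis). Points are libraries and lines are means; Lgals3 has a mean of 1519 CPM at LM day 12 and 210 CPM in control, and Havcr2 of 102 and 2.5 CPM.

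T, NK and innate lymphoid cells of LM day 12 had higher levels of inhibitory receptors and of genes of regulatory T cells than those of control. Havcr2, which codes for the receptor TIM-3 (ENSMUSG00000020399, chromosome 11, 46454935 to 46481255, GRCm38), rose from 2.5 ± 2.25 CPM (SD, n = 3) to 102 ± 23.0 CPM (n = 3; log2 fold change 5.25, SE 0.627, adjusted p = 2.75e-04). Lag3 rose by a log2 fold change of 4.69 (SE 0.570), Pdcd1, which codes for PD-1, by 2.27 (SE 0.271) and Tigit by 2.79 (SE 0.476). Of 8 exhaustion and checkpoint genes 6 rose, 7 when adjusted over the list alone (camera adjusted p = 1.41e-06; adjusted p = 0.181 with an estimated correlation). Of 6 regulatory T cell genes 4 rose, 5 when adjusted over the list alone (camera adjusted p = 3.54e-04; adjusted p = 0.208 with an estimated correlation). Among them were the lineage factor Foxp3 (2.62, SE 0.5, adjusted p = 0.00538), Ctla4 (3.59, SE 0.587, adjusted p = 0.00400) and Tnfrsf4, which codes for OX40 (4.33, SE 0.472, adjusted p = 2.18e-04).

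Gzmb, a protease of cytotoxic granules, rose from 119 ± 15.4 to 710 ± 279 CPM (log2 fold change 2.58, SE 0.258, adjusted p = 1.71e-05). Of 9 cytotoxic effector genes 1 rose, 1 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0595, and adjusted p = 0.452 with an estimated correlation). Of 18 cell cycle genes 10 rose, 16 when adjusted over the list alone (camera adjusted p = 6.54e-09; adjusted p = 0.274 with an estimated correlation). Examples were Mcm6 of the replication helicase (1.51, SE 0.177) and Mcm3 of the same complex (1.76, SE 0.282). Of 17 immediate early and heat shock genes, which are known to respond to tissue dissociation, 10 fell, 16 when adjusted over the list alone (camera adjusted p = 3.59e-10; adjusted p = 0.239 with an estimated correlation). They included Junb (-2.28, SE 0.249) and Dusp1 (-1.92, SE 0.254). Of 16 glycolysis and hypoxia genes 5 rose, 10 when adjusted over the list alone (camera adjusted p = 1.51e-04; adjusted p = 0.181 with an estimated correlation), with Pgk1 at 1.80 (SE 0.203). The cytokine gene Tnf fell (-1.51, SE 0.239), within a list of inflammatory genes of which 4 fell and 1 rose of 12 (camera adjusted p = 0.110).

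In this class 678 genes rose and 871 fell, 1549 of 10174 tested. Cluster 6, led by Trac and Cd3e, held 29.4% of its cells in control, 30.7% at LM day 7 and 68.1% at LM day 12 (26.0% to 33.8%, 18.8% to 44.5% and 60.8% to 71.1% of single libraries). Cluster 22, led by Trdc, held 31.9%, 22.3% and 6.90%. Cluster 23 held 22.6% in control and 34.2% at LM day 7, and 3.4%, 0.8% and 3.6% in LM day 12 libraries 1, 2 and 3. Within cluster 6 alone 308 genes passed, 254 of them shared in direction. There Havcr2 stood at 4.90 (adjusted p = 0.00411), Pdcd1 at 2.80 (adjusted p = 0.00138) and Foxp3 at 1.34 (adjusted p = 0.176). The calls of Tigit (2.08, adjusted p = 0.0851) and Tnf (-0.98, adjusted p = 0.0704) also ended there. Endothelial transcripts fell in this class as well, such as Tie1 (-5.00, SE 0.624; -7.31 to -4.23 over the fits without 1 library) and Adgrf5 (-4.97, SE 0.512). Of 9 abundant neutrophil transcripts 1 fell, 8 when adjusted over the list alone (camera adjusted p = 3.04e-07; adjusted p = 0.293 with an estimated correlation). Of 10 mitochondrially encoded genes 1 fell, 1 when adjusted over the list alone (median -0.42; camera adjusted p = 0.0241; adjusted p = 0.445 with an estimated correlation). Of 4 haemoglobin genes 0 passed over all genes in edgeR's test and 4 fell when adjusted over the list alone (camera adjusted p = 0.0207; adjusted p = 0.452 with an estimated correlation). With estimated free RNA taken off, 945 genes passed, 866 of them shared in direction, and 1114 passed without the female library.

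Neutrophils of LM day 12 had higher levels of interferon-inducible genes. Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008, GRCm38) rose from 19.2 ± 2.70 CPM (SD, n = 3) to 1225 ± 1170 CPM (n = 3; log2 fold change 6.0, SE 1.0, adjusted p = 0.0120), a call lost without control 1 or 2 (5.03 to 6.55 over the fits without 1 library). Gbp5, of the same family, rose by a log2 fold change of 7.51 (SE 1.40, adjusted p = 0.0203), a call lost without control 1, 2 or 3 or LM day 12 library 2 (6.29 to 8.11). Cxcl9, a chemokine for T cells, rose from 1.08 ± 0.545 to 62.8 ± 33.4 CPM (5.97, SE 0.767, adjusted p = 0.00305). Over the 3 classes in which Cxcl9 rose its level was 0.998 times that which free RNA from other cells would give. Cdkn1a, an inhibitor of cell division, rose from 35.4 ± 7.71 to 222 ± 112 CPM (2.64, SE 0.376, adjusted p = 0.00334). Of 13 interferon-gamma-inducible genes 11 rose, 13 when adjusted over the list alone (camera adjusted p = 3.91e-08; adjusted p = 0.640 with an estimated correlation). Of 18 type I interferon genes 3 rose, 14 when adjusted over the list alone (camera adjusted p = 1.84e-04; adjusted p = 0.640 with an estimated correlation), among them Stat2 (1.88). Of 10 genes of MHC class I presentation 4 rose, 7 when adjusted over the list alone (camera adjusted p = 6.57e-04; adjusted p = 0.640 with an estimated correlation), among them the regulator Nlrc5 (2.73) and the peptide transporter Tap1 (1.93). The Stat2, Nlrc5 and Tap1 calls were each lost without any 1 of control 1, 2 or 3 or LM day 12 library 2 or 3, with values of 1.31 to 2.33, 1.75 to 3.29 and 1.27 to 2.42.

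In neutrophils 311 genes rose and 210 fell, 521 of 10614 tested. Left out 1 at a time, control 1, 2 and 3 gave 184, 130 and 327 genes, and LM day 12 library 1, 2 and 3 gave 2025, 125 and 176. Cluster 5, led by Il1b and Ccrl2, held 24.9% of neutrophils in control and 63.6% at LM day 12, with 22.0%, 90.5% and 80.9% in LM day 12 libraries 1, 2 and 3. Cluster 0, led by the granule genes Ltf and Ngp, held 40.7% in control (29.0% to 44.9% of single libraries) and 16.2% at LM day 12, with 32.5%, 6.40% and 8.40% in LM day 12 libraries 1, 2 and 3. Within cluster 5 alone 673 genes passed, 265 of them shared in direction. There Gbp2 stood at 5.49, Stat2 at 2.14, Nlrc5 at 2.26 and Tap1 at 1.95, each past the threshold in edgeR's test, and Gbp5 was not fitted. At clustering resolution 2.0 the neutrophils of LM day 12 libraries 1, 2 and 3 numbered 444, 341 and 138, against 449, 472 and 345 here. That resolution had an unnamed cluster of 378 cells with 2 neutrophil markers higher than in other cells, led by Tnf and Ccrl2. Gene tests were not run at that resolution, so cluster 5 may hold cells of unsure identity. Xist stood at 101 ± 80.8 CPM (SD, n = 3) at LM day 12 and rested on 1 UMI in control, with a ratio of 1210 (exact 95% interval 216 to 48100; log2 fold change 8.89 to 11.07 over the fits without 1 library). Of its UMIs at LM day 12, 152 came from the female library 3 and 49 and 47 from libraries 1 and 2. With estimated free RNA taken off, 42 genes passed, 32 of them shared in direction. Of the 521 genes 319 could be fitted then, and 300 kept their sign. Gbp2 passed at 6.51 (adjusted p = 0.0484). The calls of Cdkn1a (2.81, adjusted p = 0.0896), Stat2 (2.13, adjusted p = 0.0627), Nlrc5 (2.91, adjusted p = 0.0955), Tap1 (2.06, adjusted p = 0.111) and Xist (9.20, adjusted p = 0.0629) ended, with changes close to those before. Gbp5 and Cxcl9 were not fitted.

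Fibroblasts of LM day 12, from 2 libraries with at least 20 such cells, had higher levels of Chl1, a cell adhesion molecule (ENSMUSG00000030077, chromosome 6, 103510586 to 103750211, GRCm38), at 264 ± 6.36 CPM (SD, n = 2) against 2.13 ± 1.84 CPM (n = 3) in control (log2 fold change 6.92, SE 0.431, adjusted p = 2.36e-07). The metal transporter gene Slc39a14 rose from 34.3 ± 11.9 to 324 ± 113 CPM (3.25, SE 0.307, adjusted p = 5.64e-05). LM day 12 libraries 1 and 2 held 29 and 51 fibroblasts. Xist stood at 73.7 and 47.9 CPM in them, from 15 and 13 UMIs. In all cells outside the Y-negative class of these libraries it stood at 27.0 and 26.7 CPM. Whether Y-negative cells among the fibroblasts account for part of the rises was not tested. Of 10 genes of MHC class I presentation 2 rose, 5 when adjusted over the list alone (camera adjusted p = 1.93e-04; adjusted p = 0.324 with an estimated correlation), namely H2-K1 (1.59) and H2-D1 (1.08). Of 18 glycolysis and hypoxia genes 2 rose, 8 when adjusted over the list alone (camera adjusted p = 1.04e-05; adjusted p = 0.405 with an estimated correlation), Eno1 among them (2.11). Flt1, a receptor of endothelial cells, was 10.7 times higher in control (exact 95% interval 2.94 to 89.2), with 2 UMIs at LM day 12. Its call was lost without control 1 or 2 or either LM day 12 library, and with DESeq2 (adjusted p = 0.0867). In all 29 genes rose and 9 fell of 10086 tested; without LM day 12 library 1 or 2 the count was 227 or 10. The H2-K1 call was lost without control 2 or LM day 12 library 2 (1.09 to 1.94 over the fits without 1 library). The H2-D1 call was lost without any 1 of the 3 control libraries or LM day 12 library 2 (0.99 to 1.16), and the Eno1 call without LM day 12 library 2 (1.86 to 2.36).

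In endothelial cells 16 genes rose and 9 fell, 25 of 11887 tested. Ubd, an interferon-inducible ubiquitin-like modifier, stood at 196 ± 153 CPM (SD, n = 3) against 0.718 ± 0.566 CPM (n = 3; log2 fold change 7.93, SE 1.10, adjusted p = 0.0315). Without control 1, 2 or 3 or LM day 12 library 2 this call was lost (7.27 to 8.74 over the fits without 1 library), and the counts of genes were 4, 4, 4 and 5. Without LM day 12 library 1 or 3 they were 346 and 118. Of 15 interferon-gamma-inducible genes 0 passed over all genes in edgeR's test and 12 rose when adjusted over the list alone. Of 18 cell cycle genes 0 passed and 10 rose when adjusted over the list alone (camera adjusted p = 9.11e-05 and 1.16e-06; adjusted p = 0.596 for each with an estimated correlation). In B lineage cells 19 genes rose and 16 fell, 35 of 8901 tested. Fkbp5, a gene induced by glucocorticoids, stood at 2.26 (SE 0.362, adjusted p = 0.00619), a call lost without LM day 12 library 3 (1.55 to 2.68). The proteoglycan gene Vcan stood at 5.16 (SE 0.678) and Spp1, osteopontin, at 3.31 (SE 0.421). Over the 5 and 4 classes in which they rose, Vcan and Spp1 stood at 1.40 and 0.882 times the level that free RNA would give. Ptprb, an endothelial phosphatase gene, was 40.3 times higher in control B lineage cells (exact 95% interval 7.17 to 1600), with 1 UMI at LM day 12.

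In monocytes 9 genes rose and 15 fell, 24 of 4872 tested, including the transcription factor gene Tcf7l2 (log2 fold change 3.61, SE 0.786, adjusted p = 0.0469), lost without control 2 or 3 or LM day 12 library 2 or 3 (3.08 to 4.66). Ptprb had 58 UMIs in control monocytes and 0 at LM day 12, at least 5.84-fold lower against a floor of 3 counts over the group, a call lost without control 1 or 2 or any 1 LM day 12 library. The B lineage count was 16, 60, 777 and 14 without control 2, control 3, LM day 12 library 1 and LM day 12 library 2. The monocyte count was 40, 12, 39, 4 and 1 without control 1, 2 and 3 and LM day 12 library 2 and 3. With estimated free RNA taken off 0, 2 and 6 genes passed in endothelial, B lineage and monocyte cells. Of the 25, 35 and 24 genes 13, 14 and 19 could be fitted then, and 12, 13 and 19 kept their sign. The calls of Ubd (7.82, adjusted p = 0.118) and Tcf7l2 (4.00, adjusted p = 0.0846) ended. Within the endothelial cluster 9 alone Ubd stood at 9.65 (adjusted p = 0.0794).

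Hmga2, an architectural chromatin protein (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469, GRCm38) and a leading gene of the Y-negative cluster 1, passed the test in 6 classes at LM day 12 against control. Over these 6 classes Hmga2 stood at 0.815 times the level that free RNA would give, and with free RNA subtracted it was not fitted. It stood at 66.4 ± 35.6 CPM (SD, n = 3) in macrophages, 112 ± 19.3 in T, NK and innate lymphoid cells, 120 ± 25.8 in neutrophils and 75.7 ± 14.8 in endothelial cells, and rested on 1, 2, 3 and 1 UMIs in control. The ratios to control were 157 (exact 95% interval 28.1 to 6200), 207 (57.3 to 1720), 548 (186 to 2670) and 931 (165 to 37000). In fibroblasts it was at least 151-fold higher than in control, where it had 0 UMIs, against a floor of 3 counts over the group, a call not made by DESeq2 (adjusted p = 0.376). In B lineage cells it rose from 1.59 ± 2.76 to 86.5 ± 41.6 CPM (log2 fold change 6.0, SE 0.839, adjusted p = 0.00619; 5.21 to 9.35 over the fits without 1 library), likewise not called by DESeq2 (adjusted p = 0.231). Against LM day 7 its ratio was 250 (44.9 to 9890) in macrophages, its log2 fold change was 6.28 (SE 0.484; 5.73 to 8.23 over the fits without 1 library) in T, NK and innate lymphoid cells, and it was at least 104-fold higher in fibroblasts (not called by DESeq2, adjusted p = 0.406). Spp1, osteopontin, rose in T, NK and innate lymphoid cells against control (log2 fold change 5.44, SE 0.566, adjusted p = 3.87e-05). Over the 4 classes in which Spp1 rose its level was 0.882 times that which free RNA would give. In this class Spp1 was not fitted with free RNA subtracted.

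**Figure D4:**
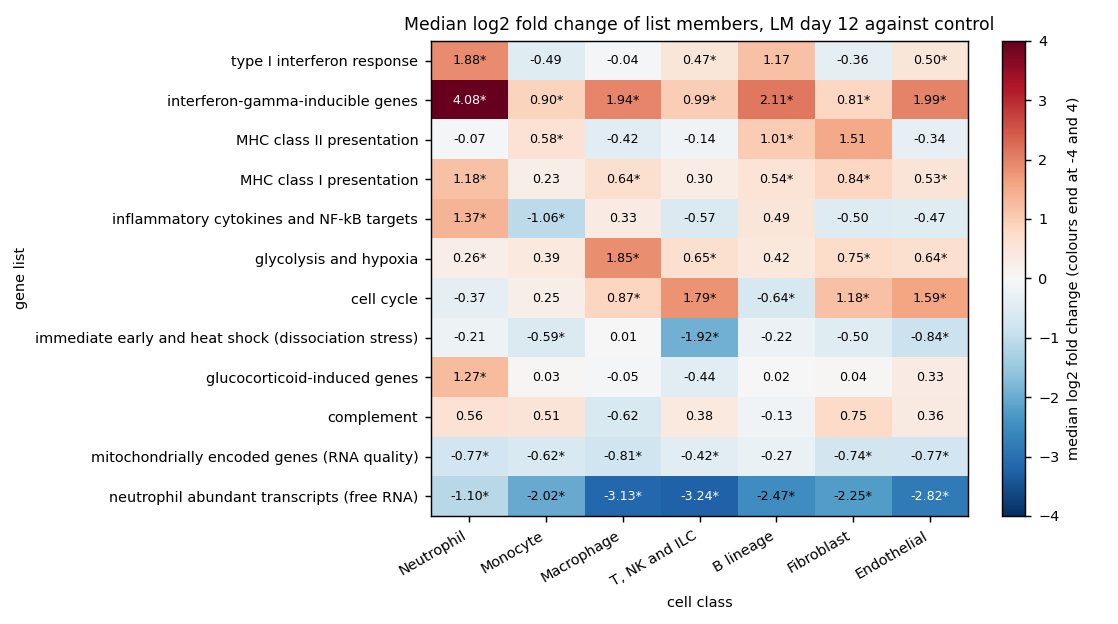
Median log2 fold change between LM day 12 and control (colour and number) of the measured genes of 12 lists (y axis) in 7 classes (x axis; ILC, innate lymphoid cells). An asterisk marks an adjusted p under 0.05 in limma's camera test with a preset correlation, and the interferon-gamma-inducible list has a median of 4.08 in neutrophils, and the abundant neutrophil transcripts have negative medians in all 7 classes, -3.24 in T, NK and innate lymphoid cells.

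The comparison of LM day 12 with LM day 7 asked which genes change within each class over the course of the disease. In macrophages Arg1 stood at 809 ± 247 CPM (SD, n = 3) at LM day 12 and 1.19 ± 2.38 CPM (n = 4) at LM day 7. Lgals3 rose from 329 ± 63.3 to 1519 ± 61.6 CPM (log2 fold change 2.21, SE 0.220). Vegfa rose by 4.41 (SE 0.468, adjusted p = 5.77e-05) and Cd209g, a C-type lectin gene, fell (-5.71, SE 1.29), a call lost without LM day 12 library 2 (-7.62 to -5.05 over the fits without 1 library). Within cluster 12 alone Lgals3 stood at 0.26 and Cd209g at -0.62, neither past the threshold. Of 17 glycolysis and hypoxia genes 16 rose, 16 when adjusted over the list alone (camera adjusted p = 9.45e-11; adjusted p = 0.0251 with an estimated correlation). Of 9 resident dural macrophage genes 4 fell, 5 when adjusted over the list alone (camera adjusted p = 8.93e-04; adjusted p = 0.492 with an estimated correlation). In T, NK and innate lymphoid cells Gzmb rose from 82.2 ± 13.6 to 710 ± 279 CPM (3.09, SE 0.239, adjusted p = 2.29e-06). Tnfrsf4 rose by 3.56 (SE 0.399) and Foxp3 by 3.07 (SE 0.479), the latter not past the threshold within cluster 6 alone (1.82, adjusted p = 0.0618). Of 8 exhaustion and checkpoint genes 7 rose, 8 when adjusted over the list alone (camera adjusted p = 1.50e-06; adjusted p = 0.181 with an estimated correlation).

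Of the 13 interferon-gamma-inducible genes measured in neutrophils 12 rose between LM day 7 and LM day 12, 13 when adjusted over the list alone (camera adjusted p = 3.91e-08; adjusted p = 0.640 with an estimated correlation). Cxcl9 stood at 4.75 (SE 0.612, adjusted p = 0.00191) and Gbp2 at 5.55 (SE 0.865, adjusted p = 0.00855). In fibroblasts Chl1 stood at 264 ± 6.36 CPM (SD, n = 2) at LM day 12 and rested on 2 UMIs at LM day 7, with a ratio of 446 (exact 95% interval 121 to 3730). Counts of changed genes were 709 in neutrophils, 5 in monocytes, 2478 in macrophages, 1874 in T, NK and innate lymphoid cells, 32 in B lineage cells, 54 in fibroblasts and 129 in endothelial cells. Without LM day 7 library 2 or LM day 12 library 3 macrophages had 1338 and 1630 genes. Without LM day 12 library 3 T, NK and innate lymphoid cells had 1178. Without LM day 7 library 1, 2 and 4 and LM day 12 library 1, 2 and 3 neutrophils had 409, 268, 180, 2371, 114 and 123 genes. Endothelial cells had 22, 21, 14, 590, 27 and 221. The same fits gave 13, 12, 13, 688, 9 and 16 genes in B lineage cells, which had 75 without LM day 7 library 3. Monocytes had 3, 16, 2, 19 and 1 without LM day 7 library 2, 3 and 4 and LM day 12 library 1 and 3. Fibroblasts had 26, 33, 31, 269 and 10 without LM day 7 library 2, 3 and 4 and LM day 12 library 1 and 2. With estimated free RNA taken off, 21 genes passed in neutrophils, 0 in monocytes, 1505 in macrophages, 1057 in T, NK and innate lymphoid cells, 1 in B lineage cells and 0 in endothelial cells.

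Between LM day 7 and control edgeR's test made 2 gene calls over the 7 classes. Osm, a cytokine of the interleukin-6 family, fell in monocytes from 248 ± 27.8 CPM (SD, n = 3) to 85.0 ± 32.0 CPM (n = 4; log2 fold change -1.57, SE 0.274, adjusted p = 0.0325). The call was lost without any 1 of control 1 or 2 or the 4 LM day 7 libraries (-1.70 to -1.27), with DESeq2 (adjusted p = 0.0612) and with the replicate block. Pglyrp1, a peptidoglycan-binding protein of neutrophil granules, rose in B lineage cells from 53.8 ± 11 to 167 ± 41.0 CPM (1.64, SE 0.25, adjusted p = 0.0201). The call was lost without control 1, 2 or 3 or LM day 7 library 1, 3 or 4 (1.48 to 1.77). It was also lost with estimated free RNA taken off, where the change was larger (3.07). Abundant neutrophil transcripts had positive medians in the B lineage (1.2, camera adjusted p = 9.75e-06; adjusted p = 0.831 with an estimated correlation), where 0 of 9 genes passed over all genes in edgeR's test and 2 rose when adjusted over the list alone.

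In macrophages of LM day 7, 0 of 10 glucocorticoid-induced genes passed over all genes in edgeR's test and 3 rose when adjusted over the list alone (camera adjusted p = 0.00476; adjusted p = 0.468 with an estimated correlation). Fkbp5 stood at 1.04 (SE 0.229) and Tsc22d3 at 0.85 (SE 0.220). Likewise 0 of 17 immediate early and heat shock genes passed and 5 fell when adjusted over the list alone (camera adjusted p = 1.00e-05; adjusted p = 0.492 with an estimated correlation). Fos stood at -1.0 (SE 0.231) and Jun at -1.0 (SE 0.255). Over all genes edgeR's test called 0 in neutrophils, macrophages, T, NK and innate lymphoid cells, fibroblasts and endothelial cells. In these 255, 352, 429, 292 and 271 genes had an unadjusted p under 0.05, and DESeq2 called 17, 0, 7, 2 and 0. With no filter on low counts edgeR called 48, 44, 24, 24 and 0 in these classes, and 17 in monocytes and 18 in B lineage cells. In T, NK and innate lymphoid cells 1 gene passed without LM day 7 library 1, and in fibroblasts 4 passed without control 2. Ccl3, a chemokine gene, stood at 62.4 ± 9.11 CPM (SD, n = 4) in T, NK and innate lymphoid cells of LM day 7 and 162 ± 32.4 CPM (n = 3) in control (log2 fold change -1.38, SE 0.211, adjusted p = 0.0713), and at 0.11 within cluster 6 alone.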

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

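All tests of explanations in this part, the splits of the samples among them, were chosen after the results were seen.

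In 3 of 22 groups of 4 LM day 7 libraries tested by Dixon's ratio, 1 library lay far from the others; chance gives about 1 in 20 such groups. The share of endothelial cells was 19.7% in LM day 7 library 3 and 13.04% to 13.5% in the other 3. The share of unnamed cells was 10.6% in library 1 and 3.25% to 3.63% in the others. In library 2, 779 barcodes were removed by the cell filter, against 59 to 171 in the others.

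Splits of the samples that ignore the groups were fitted the same way. For LM day 12 against LM day 7, of 35 splits, 1, the real one, gave as many classes (11, highest other 1) and as many genes in neutrophils (709, highest other 91), macrophages (2478, highest other 974), T, NK and innate lymphoid cells (1874, highest other 296) and endothelial cells (129, highest other 11). This share lies under the bound of 0.05 set for chance. It is the smallest that 35 splits can give and was not adjusted over the results, so it does not exclude chance by itself. As many genes came from 2 splits in B lineage cells, where 1 other gave 33, and from 3 in monocytes, where the highest other gave 15, so that the bound was not met there. In the 6 classes split for genes the highest other split set LM day 7 library 3 with the LM day 12 libraries. For LM day 12 against control the 10 splits are too few for a share under 0.05, with 1 of 10 as large in each case. The real and highest other counts were 10 and 0 classes, and 521 and 0 genes in neutrophils, 24 and 0 in monocytes, 1997 and 2 in macrophages, 1549 and 2 in T, NK and innate lymphoid cells, 35 and 2 in B lineage cells and 25 and 1 in endothelial cells. For LM day 7 against control, all 35 splits gave at least the real count of 0 for classes and for neutrophil, macrophage, T, NK and innate lymphoid, fibroblast and endothelial genes, with highest others of 1, 0, 5, 1, 3 and 0. In monocytes 3 of 35 and in B lineage cells 5 of 35 splits gave as many as the real 1 gene, with highest others of 3 and 4.

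The Y-negative cells of LM day 12 libraries 1 and 2 are the first pattern weighed. Missed Y transcripts in shallow cells are excluded for clusters 4, 13 and 18, whose pooled median UMI count was at least 5.87 times that of the other cells of the library (4.17 to 10.0 times for single clusters), and for the low-UMI cluster 1, where Xist in CPM was at least 8.45 times that of the other cells. Loss of the Y chromosome from host cells is excluded for clusters 1 and 4 by Xist at 8.45 and 10.2 times or more, with lowest 95% limits from resampled cells of 7.00 and 8.94. In clusters 13 and 18 Xist at 4.90 and 3.88 times or more argues against it, with lowest limits of 4.28 and 2.37, above the bound of 2 times. Resampled cells are not replicates, and cluster 18 of library 2 held 33 cells, with Y-linked genes at 43.3 CPM. Cells of a female mouse mixed into the libraries in proportion are excluded by Y transcripts of the other classes at 83.7% or more of the control level. The shallow test was first run on all clusters together and was divided after its first result, and the Xist test first asked for 5 times, which clusters 13 and 18 missed in library 2 only (11.8 and 10.0 times in library 1). Cells of female origin absent from control, such as implanted tumour cells, are a candidate explanation; the cell line and its sex are not given in the sources used here, and this was not tested.

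The lower shares of endothelial, fibroblast, mural and Schwann or oligodendrocyte cells at LM day 12 are the second pattern. With Y-negative cells left out of the total 4 of 4 classes still passed, and with macrophages left out as well 4 of 4 did, which excludes a closed sum from these cells as the whole cause. With every removed barcode of a LM day 12 library counted into these classes their summed share reached at most 10.9%, against at least 17.2% in control libraries with none added. This excludes the cell filter alone. The total still held the Y-negative cells and macrophages, so the filter together with a closed sum is not excluded. Fewer such cells in the tissue, a lower yield from digestion, and cells lost before capture may each underlie the lower shares and were not tested. TMM factors over the classes ended 3 of the 4 calls, with smaller changes and similar spread. Endothelial cells went from -2.88 (SE 0.583) to -1.07 (SE 0.474) and fibroblasts from -3.59 (SE 0.625) to -1.49 (SE 0.630). Schwann cells or oligodendrocytes went from -2.68 (SE 0.619) to -0.89 (SE 0.478).

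Genes that rose in 3 or more classes at LM day 12 against control are the third pattern, for which RNA set free from other cells was tested. Of 18 such genes with their highest level in Y-negative cells, 55.6% (exact 95% interval 30.8% to 78.5%) lay within 2 times of the level that free RNA would give, which decides nothing for these genes as a set; Hmga2, in 6 classes, stood at 0.815 of that level. Of 34 such genes highest in another class, 20.6% (8.70% to 37.9%) did so, with a median of 7.40 times that level. This argues against free RNA as the cause for most of them. Gbp5, Tap1 and Fkbp5 were among those over 2 times that level, and Cxcl9, Vcan and Spp1 were within it. The interval takes the genes as independent, though several share a list, and a median over classes does not decide a single class. The estimated share was too low for Xist in neutrophils of LM day 12 library 2, so the level that free RNA would give can be too low. The test first took genes that rose in at least 4 classes, with 5 of 5 and 3 of 8 genes within the bound (47.8% to 100% and 8.52% to 75.5%), too few to decide, and the number of classes was lowered to 3 before the result at 3 was seen. The sex of LM day 12 library 3, its day and the disease cannot be separated for genes that this library decides, and a biological cause remains a hypothesis.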

How the results depend on the processing

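The restriction to 1 cluster of a class, the subtraction of free RNA, the totals without Y-negative cells or macrophages and the permutation test of the absolute difference were chosen after the results were seen; the other alternatives here were fixed beforehand.

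Of the values for single classes and genes, 1023 values under settings fixed beforehand kept direction and side of the threshold, 124 kept direction and no longer passed, 5 passed newly and 5 reversed; of the added ones 132, 39, 0 and 4 did so. Size factors in place of TMM left all 78 named genes on their side. Reversed with TMM factors over the classes were the mast cell or basophil share between LM day 12 and LM day 7 (0.00103) and the monocyte share against control (0.0429) and LM day 7 (0.26), and at resolution 2.0 the monocyte shares (1.36 and 1.66). Within cluster 12 alone Thbs1 (-0.63), Cd163 (0.62) and Il1rn (-0.92) in macrophages reversed between LM day 12 and control, and within cluster 6 alone Ccl3 (0.11) between LM day 7 and control. The cause was not tested.

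The classes changed in share at LM day 12 numbered 4 against control and 3 against LM day 7 with leukocytes only. Classes other than leukocytes were not tested in that setting. Against LM day 7 there were 7 with TMM factors and 6 with Y-negative cells and macrophages left out. Two-sided exact permutation gave 0 each, with p as double the smaller tail (which cannot pass at these sizes) or on the absolute difference. List calls fell from 148 to 2 with an estimated correlation and 33 by fry. Below, counts of genes are given for LM day 7 against control, LM day 12 against control and LM day 12 against LM day 7 in this order, where they moved by over 1.5 times. DESeq2 gave 17, 1119 and 1286 in neutrophils, 0, 50 and 28 in monocytes, 7 for the first in T, NK and innate lymphoid cells, 125 and 111 for the last pair in B lineage cells, 2, 119 and 156 in fibroblasts and 492 and 696 for the last pair in endothelial cells. With no filter on low counts there were 48, 1588 and 1684 in neutrophils, 17, 168 and 100 in monocytes, 44, 3649 and 4099 in macrophages, 24 and 2393 for the first pair in T, NK and innate lymphoid cells, 18, 517 and 425 in B lineage cells, 24, 414 and 503 in fibroblasts and 188 and 273 for the last pair in endothelial cells. The stricter cell filter gave 2 for the first in neutrophils.

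With free RNA subtracted the last pair stood at 42 and 21 in neutrophils, 6 and 0 in monocytes, 1204 and 1505 in macrophages, 945 and 1057 in T, NK and innate lymphoid cells and 0 and 0 in endothelial cells; B lineage cells had 0, 2 and 1, and fibroblasts 2 and 25 for the first pair. Single clusters gave 3 for the first in neutrophils (cluster 5), 5 and 5 for the last pair in macrophages (12), 308 and 316 in T, NK and innate lymphoid cells (6), 49 and 68 in endothelial cells (9), and 2, 71 and 59 in B lineage cells (8).

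With each library left out in turn the share counts ranged over 0 to 0, 8 to 13 and 8 to 12. Gene counts ranged over 0 to 0, 125 to 2025 and 114 to 2371 in neutrophils, 0 to 2, 1 to 40 and 1 to 19 in monocytes, 0 to 0, 1017 to 2256 and 1338 to 2637 in macrophages, and 0 to 1, 1114 to 1686 and 1178 to 1999 in T, NK and innate lymphoid cells. They ranged over 0 to 1, 14 to 777 and 9 to 688 in B lineage cells, 0 to 4, 10 to 227 and 10 to 269 in fibroblasts, and 0 to 0, 4 to 346 and 14 to 590 in endothelial cells. Where 1 fibroblast library was left at LM day 12, it was assumed to vary like the other groups.

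With the replicate block, neutrophils had 2 genes for the first comparison and 367 for the last, monocytes 0, 75 and 42, B lineage cells 2, 145 and 111, endothelial cells 68 and 79 for the last pair, and T, NK and innate lymphoid cells and fibroblasts 1 each for the first. The replicate numbers did not pair the samples: over 9 pairs of same-numbered libraries the mean correlation of deviations was 0.0520 (-0.16 to 0.237), and 4 of 9 were over 0.1. Some libraries were alike across groups and numbers. Cluster 15 held 59.9%, 57.6% and 60.6% of Tph1-high cells in control 3, LM day 7 library 3 and LM day 12 library 2. Cluster 19 held 63.8%, 67.1%, 59.8% and 68.6% in control 1 and 2 and LM day 7 libraries 2 and 4, and at most 4.3% elsewhere. A batch shared in this way was not modelled or tested. Depth limits genes with few counts in a group, for which the ratio intervals span more than 10 times.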

Other observations

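The list tests in this part were fixed beforehand, and which of them to describe was decided after the results were seen.

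Between LM day 12 and control, B lineage cells had positive medians for genes of MHC class II presentation, which present peptides to helper T cells (log2 1.01), and for interferon-gamma-inducible genes (2.11). Of 10 measured genes of each list 0 passed over all genes in edgeR's test, and 6 and 7 rose when adjusted over the list alone. The camera adjusted p-values were 8.40e-05 and 5.74e-05, with an adjusted p = 0.831 for each with an estimated correlation. Clusters 21 and 35, led by progenitor genes such as Vpreb3, held 34.1% and 10.7% of B lineage cells in control, and in LM day 12 libraries 1, 2 and 3 they held 35.0%, 0% and 0% and 11.3%, 0% and 1.80%. Within cluster 8 alone the camera adjusted p-values were 0.0643 and 6.36e-05. B cell progenitor genes had a median of -1.14, and 0 of 10 passed over all genes or when adjusted over the list alone (camera adjusted p = 1.04e-04; adjusted p = 0.831 with an estimated correlation).

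In neutrophils 2 of 14 inflammatory cytokine and NF-kB target genes rose, 7 when adjusted over the list alone (camera adjusted p = 1.84e-04, and adjusted p = 0.640 with an estimated correlation). This came with a shift to cluster 5, led by Il1b and Ccrl2, which held 24.9% of neutrophils in control and 63.6% at LM day 12. The list change and this shift are not separated here. In monocytes 0 of 17 immediate early and heat shock genes, which dissociation can induce, passed over all genes in edgeR's test and 4 fell when adjusted over the list alone (camera adjusted p = 2.82e-05; adjusted p = 0.448 with an estimated correlation).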
